A study of Caenorhabditis elegans with 4 samples.

How the data were processed

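ChIP-seq libraries (anti-GFP) and input libraries of L3 animals of strain OP74 were used, 2 replicates of each. Per the labels, animals grew at 20 °C, were fixed in 2% formaldehyde for 30 min, and chromatin was sheared to 200 to 800 bp. Replicate and group were read from the sample titles.

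The deposited peak lists, made with PeakSeq on WormBase WS180 per the file headers, give a q value (a p-value adjusted for multiple tests) per peak of ChIP against the input of the same replicate. Deposited q values ran from 1.6e-16 to 0.00976 in replicate 1 and from 1.21e-17 to 0.00987 in replicate 2. The deposited alignments list every 30-base read with its match code and position, in the extended ELAND format; they are alignments and not a table of counts, and the aligner's version and settings are not stated. Reads with 1 listed position were used. Reads without a match made up 68.3%, 55.9%, 70.2% and 67.4% of ChIP replicates 1 and 2 and input replicates 1 and 2. Distinct start positions made up 86.8% and 87.6% of unique reads in ChIP and 97.6% and 97.1% in input.

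Reads were counted at their 5-prime end moved 100 bp downstream and scaled by total unique reads. Overlap of the lists was tested with 10000 random placements. ChIP was compared with the input of the same replicate by an exact conditional binomial test, with Clopper-Pearson 95% intervals, and replicates were compared by a likelihood ratio chi-square test in a Poisson model. The threshold was 0.05. P-values called adjusted were adjusted by Benjamini-Hochberg over their family of regions, motifs, hexamers, flanking positions, chromosomes or bins, and all others are unadjusted. The p-values of these tests on reads of 2 libraries compare those libraries, not conditions, and all intervals cover counting error only. Ratios used for medians had 0.5 added to both counts. Summits were the middle of the highest pile-up of 200 bp fragments.

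No genome sequence was at hand, so the bases under unique reads were rebuilt from the reads and their mismatch descriptors. This gave 58.6% of 100263754 bp, and of 31861448 bases read more than once, 0 were left open because fewer than 90% of reads gave the same base. Motifs were counted within 100 bp of summits against random windows of the same chromosome and 5% GC class with at least 50% of bases read. The plan named the number of peaks with a motif as the statistic. The rate per fully read position was reported instead, because random windows were less fully read than peaks, which favours peaks in the planned count; both are in the alternatives. Human domain sequences, written from memory, were searched with tblastn. A match was placed at an E value up to 1e-05 with a score at least 1.1 times that of the next locus. From the mesoderm set, 1 domain was left out after its result was seen. No test with it kept is given, so whether the count for the set depends on it is not shown. The genes named are the best matches and were not checked against gene models.

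The gene annotation at hand belongs to another build, so the planned comparisons over promoters, of gene lists at promoters and of peak position relative to genes were not run, and no gene list was tested. In their place, ChIP and input were compared over 1 kb bins with at least 10 reads. This used limma voom with the replicate as a block, which left 1 residual degree of freedom. The prior degrees of freedom were estimated as infinite, so the variance of a bin came from all bins together and not from its own libraries. The deviations of same-numbered ChIP and input libraries had a correlation of -0.0044 over 94560 bins, so the paired block removed little. The fit was tested on simulated Poisson counts, which vary by counting error only. It recovered 85 of 100 bins raised 4 times and 100 of 100 raised 8 times, with 2 calls among unchanged bins.

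The rule for naming regions took the 12 shared regions with the highest smaller ratio and, from each list, the 3 unshared regions with the highest ratio in their own replicate; its parts on promoters were not run. The comparisons of peak lists, reads at peaks, motifs and reads at hlh-8, their alternatives and this rule were chosen before the data were examined. The bin fit, the domain sets, the grouping of 3 E-boxes, flanking bases, any CANNTG in unshared regions, the input-matched sets for unshared regions, all-hexamer and B-box tests, chromosome counts and the search for tag reads were chosen after. An ungapped domain search was tried before tblastn and set aside. Tag reads were sought as reads without a match that code for 8 consecutive residues of GFP; 7 residues were tried first and gave too many matches to the reversed protein.

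Alternatives were removal of duplicate reads, scaling by 10 kb bins without peaks, unmoved read ends, the better-scoring 108 and 45 peaks of the lists, reciprocal overlap of 50%, summits within 200 bp, windows of 50 and 250 bp, flanks 1000 bp away, 10 kb around hlh-8, and for the bin fit no replicate block, no filter, limma-trend with a pseudocount of 1, 2 kb bins and each library left out. Domain distances of 5 and 20 kb and the set without hlh-8 were also tried. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and BLAST+ 2.17.0.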

Results

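Binding of HLH-8, the Twist-family basic helix-loop-helix (bHLH) protein of C. elegans, was measured by ChIP-seq in L3 larvae of strain OP74, which carries HLH-8 tagged with GFP and 3xFLAG. Chromatin precipitated with anti-GFP antibody formed the ChIP group (n = 2 replicates), and unprecipitated chromatin of the same preparations formed the input group (n = 2). ChIP replicates 1 and 2 held 3610139 and 2346517 reads, of which 983048 and 891884 had a unique position. The inputs of replicates 1 and 2 held 4976967 and 3765674 reads, with 1265317 and 1040697 at a unique position. The replicates are called biological in the series text, which places 1 of them in an earlier part of L3 without naming it. Coordinates are those of WormBase WS180, the build named in the headers of the peak lists.

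How far the replicates shared their binding regions was asked first. The deposited list of replicate 1 held 216 peaks with a median length of 374 bp, and that of replicate 2 held 91 peaks with a median length of 411 bp. By an overlap of at least 1 bp, 48 peaks were common to both lists, which was 22.2% of the replicate 1 list and 52.7% of the replicate 2 list. Random placement of the replicate 2 peaks on their own chromosomes gave a mean of 0.234 overlaps and at most 4 (one-sided permutation p = 0.0001, the smallest that 10000 placements can give). Merging overlapping peaks left 259 regions, of which 48 came from both lists, 168 from replicate 1 only and 43 from replicate 2 only.

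Each list was then measured in the other replicate's libraries, which had not been used to choose it. Of the 216 replicate 1 peaks, 139 (64.4%) had more ChIP than input reads in replicate 2 (exact binomial test, adjusted p under 0.05), with a median ratio of 2.44. Of the 91 replicate 2 peaks, 70 (76.9%) did so in replicate 1, with a median ratio of 3.17. In the libraries they were called in, all 216 and all 91 peaks passed, at median ratios of 4.01 and 4.11 that selection biased upward. Random regions of the same lengths had median ratios from 0.984 to 1.17, but held fewer input reads than the peaks, so their number of calls is no like control and is not compared. Regions called in replicate 1 only lay above input in replicate 2 at 160 of 168 places, with a median ratio of 2.24, and regions called in replicate 2 only lay above input in replicate 1 at all 43 places, with a median ratio of 2.15. Across the 259 regions the log2 ratios of the replicates had a Pearson r of 0.276 and a Spearman rho of 0.316; regions are not independent replicates, and selection in either list lowers this correlation.

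**Figure D1:**
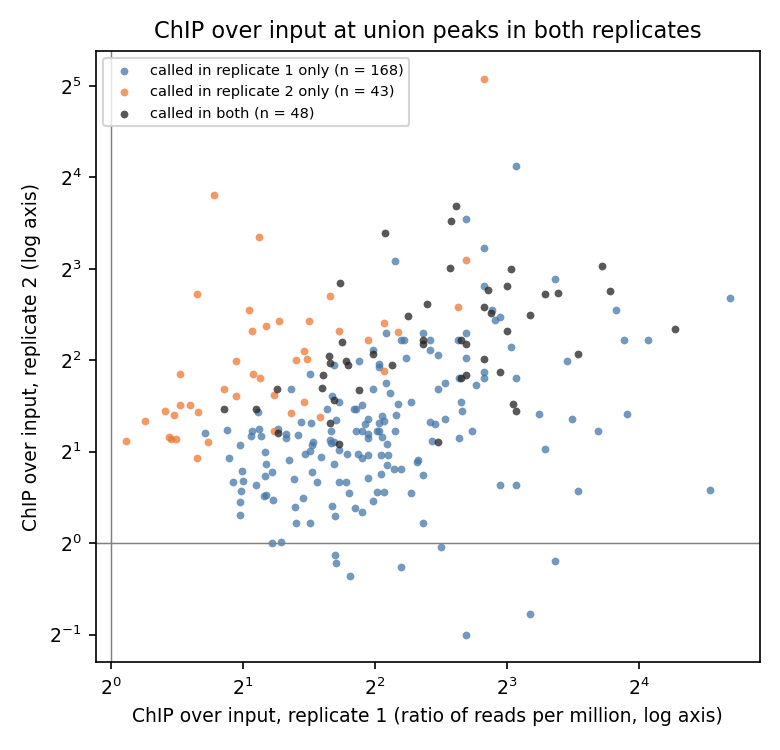
ChIP over input (ratio of depth-scaled reads, log axes) in replicate 1 and replicate 2 for the 259 merged regions, 1 point per region, coloured by the list that called it. All 48 regions called in both lists lie above a ratio of 1 in both replicates, as do 160 of the 168 regions called in replicate 1 only in replicate 2.

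The 12 shared regions with the highest smaller ratio of the 2 replicates were led by II:5877891-5878181, with a ratio of 13.2 (95% interval 4.78 to 50.7) in replicate 1 and 8.17 (2.86 to 32) in replicate 2. Next came IV:1895045-1895362, at 8.15 (3.42 to 23.6) and 7.97 (3.37 to 23), and X:5193382-5193917, at 7.98 (3.08 to 26.3) and 7.0 (2.92 to 20.3). The region IV:16385023-16385466 had the most ChIP reads of the 12 in replicate 1, 73 against 13 in input, and 41 against 7 in replicate 2. The other members were I:7200902-7201200, X:3899141-3899484, I:13500933-13501227, III:6156364-6156688, I:4080296-4080675, III:5980513-5980832, I:4942823-4943330 and IV:10512771-10513176, and the smaller ratio of these ran from 6.77 down to 5.70. All 12 had an E-box of the kinds CAGATG, CACATG or CATATG within 100 bp of the summit. At IV:1895166-1895171 a CAGATG lay 6 bp from the summit in the context GTGATCACCAGATGGTGAGGAC, and at X:3899277-3899282 a CATATG lay 6 bp from the summit in the context TTGGCAACCATATGTCCGTCAT.

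Regions called in replicate 1 only were led by III:5222401-5222601, with 20 ChIP reads against 1 input read in replicate 1 (ratio 25.7, interval 4.12 to 1067) and 11 against 2 in replicate 2 (6.42, 1.40 to 59.6). At II:6374191-6374434 the ratios were 23.2 (3.66 to 965) and 1.5 (0.497 to 4.74), and at X:14401325-14401552 they were 16.7 (4.19 to 145) and 4.67 (1.26 to 25.8). Regions called in replicate 2 only were led by X:9719156-9719466, at 33.8 (5.61 to 1382) in replicate 2 and 7.08 (1.55 to 65.7) in replicate 1. V:8555908-8556348 had 14 (4.42 to 71.1) and 1.72 (0.664 to 4.61), and X:16815379-16815767 had 10.2 (3.65 to 39.5) and 2.18 (1.05 to 4.71). None of these 6 regions differed between the replicates after adjustment (likelihood ratio chi-square test, lowest adjusted p = 0.0745).

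Over the 259 regions, 2 differed between the replicates in ChIP over input (likelihood ratio chi-square test of 4 library counts, adjusted p = 0.037 for each), and 44 did so before adjustment. With duplicate reads removed the count was 0, with 33 before adjustment. These 2 regions were singled out after their values were seen. Of them, 1 was called in replicate 1 only and 1 in replicate 2 only, while 0 of the 48 shared regions passed. Every region was chosen on these same libraries, and a call in 1 list only favours a difference. The p-values are therefore no independent test. At V:5700218-5701412 the ratio was 3.24 (2.14 to 5.0) in replicate 1 and 0.917 (0.50 to 1.66) in replicate 2. At X:6742291-6744359 it was 1.19 (0.901 to 1.58) and 2.52 (1.88 to 3.39).

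The sequence at the summits was compared with random windows of matched GC content from the same chromosomes. At shared regions, sites of CATATG were 7.61 times, CAGATG 7.12 times and CACATG 4.81 times as frequent per position as in matched windows (one-sided permutation test, unadjusted p = 0.0001 for each, the smallest that the draws can give, and adjusted p = 0.0003). The ratios were 5.48, 4.54 and 4.54 for the replicate 1 list and 5.11, 5.18 and 4.23 for the replicate 2 list. A CAGATG lay within 100 bp of the summit at 33 of 48 shared regions, against 4.53 in matched windows, and at 93 of 216 and 47 of 91 peaks of the separate lists, against 19.1 and 8.46. Among the other hexamers of the form CANNTG, CAGCTG was 3.23 times as frequent at shared regions (adjusted p = 0.0076), while CAAATG, CAACTG, CAAGTG, CAATTG and CACCTG were not past the threshold in any list. By the number of peaks with the motif, the statistic first planned, CACCTG did pass in the replicate 1 list (20 of 216 peaks against 11.8 in matched windows, one-sided permutation test, adjusted p = 0.0226), and so did CACGTG at shared regions (7 of 48 against 2.21, adjusted p = 0.0117), whose rate did not (adjusted p = 0.0564). CACGTG had ratios of 1.78 (adjusted p = 0.031) and 2.65 (adjusted p = 0.0036) in the lists of replicates 1 and 2, but these depended on the window: they were 2.77 (adjusted p = 0.0004) and 1.95 (adjusted p = 0.199) within 50 bp of the summit, and 1.16 (adjusted p = 0.359) and 1.48 (adjusted p = 0.166) within 250 bp. The comparison motif GAGAGA, common at open promoters, was also more frequent, at 2.44, 3.23 and 3.02 times in the replicate 1, replicate 2 and shared sets.

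**Figure D2:**
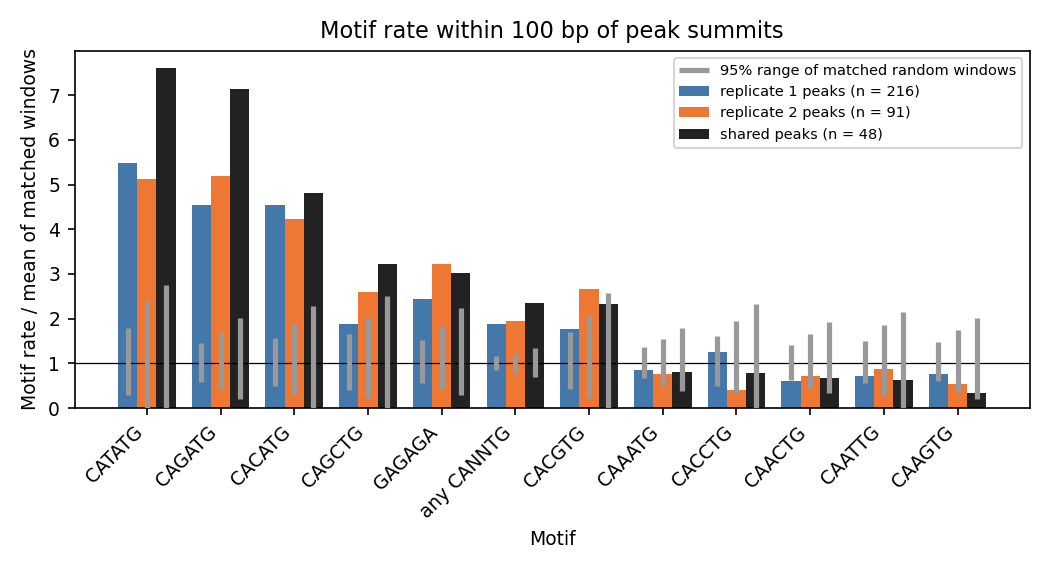
Motif rate within 100 bp of peak summits over the mean rate of GC-matched random windows, for 12 motifs in the peaks of replicate 1 (n = 216), replicate 2 (n = 91) and both lists (n = 48). Grey lines span 95% of the random draws; CATATG, CAGATG and CACATG lie above them in all 3 sets.

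Taking CAGATG, CACATG and CATATG together, 44 of 48 shared regions (91.7%) had a site within 100 bp of the summit, as had 103 of 168 regions called in replicate 1 only (61.3%) and 26 of 43 called in replicate 2 only (60.5%). Shared regions differed from the 211 others, of which 129 had a site (two-sided Fisher's exact test, p = 1.65e-05, odds ratio 6.99). These 3 motifs were grouped after their rates were seen. Sites were concentrated at the summit, with 0.880 sites per region per 100 bp at distances under 25 bp and 0.116 at 200 to 250 bp. These densities were not corrected for bases without reads, which can show no site, so part of the fall may reflect coverage. On the strand that reads CATCTG, the next base was G at 41.8% of 141 sites near summits and at 22.4% of sites outside the regions. The base before was A at 51.1% against 26.1%. These were the bases with the largest excess at their positions. Base composition as a whole differed at both positions (chi-square test, adjusted p = 4.49e-13 and 1.86e-11). It also differed 2 bases after, 2 bases before and 3 bases before (chi-square test, adjusted p = 3.18e-07, 5.99e-05 and 0.0229). For G alone, a two-sided Fisher's exact test gave p = 2.2e-07. The outside sites were not matched on GC content.

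Regions were unevenly spread over chromosomes. Chromosome I held 72 of the 259, 1.85 times its share by length (exact binomial test, adjusted p = 7.39e-07), and chromosome X held 66, 1.44 times its share (adjusted p = 0.00558). Chromosomes II and IV held 0.634 and 0.642 times their share (adjusted p = 0.0178 and 0.0135). In the replicate 2 list alone, chromosome I (1.90 times, adjusted p = 0.00598) was the only chromosome past the threshold.

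ChIP and input were also compared over 1 kb bins of the 6 nuclear chromosomes with limma. Of 94560 bins, 227 were higher in ChIP and 4 lower (adjusted p under 0.05), and 3903 and 1607 were so before adjustment. These calls rest on a variance shared by all bins and do not measure the spread of replicates at single bins. The higher bins covered 143 of the 259 regions with 147 bins, and 80 lay outside all of them. A bin over IV:16385001-16386000 had a log2 ratio of 2.27 (SE 0.32), and a bin over II:160001-161000 had 2.55 (SE 0.36). The bin X:8117001-8118000 next to the match to hlh-8 had 1.87 (SE 0.24). Among the 80 bins outside the regions, 45 had at least 1 of the 3 E-boxes within 100 bp of their read maximum, against 13.9 in matched windows. That count was not tested, and it favours windows that are more fully read. Per fully read position, sites were 2.95 times as frequent as in matched windows (one-sided permutation p = 0.0001, the smallest the draws can give). Leaving out 1 library left a lone library in its group, so the spread came only from the group that kept 2. The counts of such fits therefore cannot show whether the calls rest on the inputs or on the ChIP libraries. Without the minimum of 10 reads no bin passed (0, with 3540 higher before adjustment). The 4 lower bins were adjacent, at I:15064001-15068000 near the right end of the chromosome, with log2 ratios of -0.62, -0.99, -0.81 and -0.53. Reads per library in these bins ran from 718 to 3200, against medians of 7 to 12 per bin of chromosome X. They are thus unlike ordinary bins, and the cause of this depth was not tested. With duplicates removed 1 bin was lower.

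Whether regions lay near genes of the mesoderm was examined with conserved protein domains, placed on the bases read in these libraries because the gene positions at hand belong to another genome build. Of 12 mesodermal domains searched, 8 were placed, and 3 of them had a region within 10 kb, against 0.496 for random placement (one-sided permutation p = 0.0106). The set had been changed after its results were seen, so this p-value describes the set and is no independent test. The call did not hold within 20 kb (3 of 8, permutation p = 0.0539) or without hlh-8 (2 of 7, permutation p = 0.0615). The bHLH domain of hlh-8 (C02B8.4) was placed at X:8118697-8118822, inside the shared region X:8117611-8119061, whose ratios were 3.16 (2.39 to 4.22) and 3.91 (2.94 to 5.26). The best match to the kinase domain of FGFR1, taken as egl-15 (F58A3.2), began at X:11019792, and X:11015713-11016106 lay 3.69 kb upstream of it with ratios of 7.08 (3.30 to 17.4) and 3.50 (1.52 to 9.01). The match to the SRF domain, taken as unc-120 (D1081.2), began at I:8460386 with the shared region I:8459096-8459416 lying 0.970 kb upstream, at 5.58 (2.25 to 16.6) and 2.15 (1.05 to 4.61). Distances are to the domain matches and not to the starts of the genes, so a region upstream of a match may lie inside the gene. No region lay within 10 kb of the matches taken as ceh-24, mls-1, unc-62, let-381 and pop-1, at distances from 44.5 to 458 kb. A comparison set held genes outside the mesoderm set, including let-60, sem-5, mpk-1 and hsf-1, which are not limited to other tissues. In it, 1 of 10 placed domains had a region within 10 kb, that of let-60 (ZK792.6), against 0.523 for random placement (one-sided permutation p = 0.419). The difference between the sets did not pass the threshold (two-sided Fisher's exact test, 3 of 8 against 1 of 10, p = 0.275).

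Whether the tagged strain carried more than the usual dose of hlh-8 was asked with the input reads of that locus. Within 25 kb of the hlh-8 match, input reads per 1 kb bin were 2.36 times (95% interval 2.24 to 2.49) the median of chromosome X in replicate 1 and 2.67 times (2.53 to 2.82) in replicate 2; within 10 kb they were 3.36 and 3.83 times. The ChIP libraries had 2.96 and 3.50 times within 25 kb. By means over 3 bins of at least 1.5 times the median in both inputs, the raised part around the match was X:8102001-8130000, where the inputs averaged 3.30 and 3.72 times the median and ChIP over input was 1.30 and 1.45. Bins within it went as low as 1.08 times in input replicate 1, at X:8115001-8116000, and 1.5 times in input replicate 2, at X:8102001-8103000. Raised bins also occurred beyond both edges, with 3.92 and 3.40 times the median in the inputs at X:8136001-8137000 and 3.75 and 2.90 times at X:8084001-8085000, and the 20 kb on either side averaged 1.30 and 1.29 times to the left and 1.36 and 1.38 times to the right. Of 3576 other windows of 28 kb on the nuclear chromosomes, 0 had as high a median in both inputs as this 3.04, and the highest, II:6832001-6860000, had 2.00. Those windows lay on a fixed grid, while the edges around hlh-8 were fitted to its input reads, which favours the part around hlh-8.

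**Figure D3:**
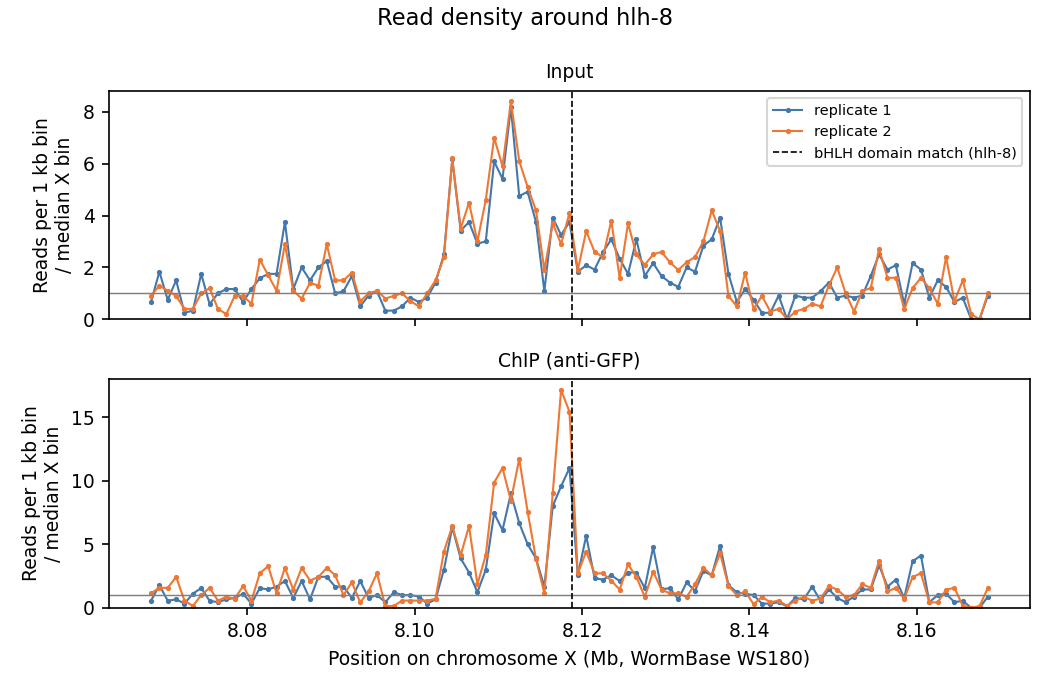
Reads per 1 kb bin over the median bin of chromosome X, around the hlh-8 match (dashed line), in input (upper panel) and ChIP (lower panel), 1 line per replicate, against position in Mb. The inputs average 3.30 and 3.72 times the median over X:8102001-8130000.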

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

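Of the tests in this part, the comparison of GFP-coding reads with the raised copy number was chosen after the reads were seen, and the GC test was chosen before its result was seen.

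Reads without a match in the genome, which no comparison of the results used, held reads that code for GFP. There were 30 in ChIP replicate 1, 13 in ChIP replicate 2, 22 in input replicate 1 and 16 in input replicate 2, against 0, 0, 0 and 2 for the reversed GFP protein and a limit of 3 that a count of 0 allows. Per kb of coding sequence they reached 2.57 times (95% interval 1.61 to 3.89) and 2.24 times (1.28 to 3.64) the chromosome X median in the inputs. With GFP divided into 3 equal parts, the part nearest the C terminus held 23 of 30, 11 of 13, 12 of 22 and 3 of 16 of these reads.

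The raised input around hlh-8 was not explained by GC content: against chromosome X bins of the same GC content, the smaller ratio of the inputs was still 3.29. Extra copies of hlh-8 that carry the tag may account for it, since GFP-coding reads had 0.825 (replicate 2) and 1.12 (replicate 1) times the density that the block's excess over 1 copy predicts. The number of copies stays open, since the counts are small. The design has no group without the tag, so no explanation beyond these was tested.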

How the results depend on the processing

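The alternatives for the bin fit and the domain sets, and the motif rate reported in place of the planned number of peaks with a motif, were chosen after seeing the data; the others were planned.

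Of 180 alternative values for 46 results, 166 kept their side of the threshold or stayed within their limits. For the 36 combinations of motif and peak set, 136 of 142 did so, including every value for CAGATG, CACATG and CATATG. Of the motif results past the threshold, 0 reversed direction. Direction was not compared for motifs short of the threshold, and some of these crossed a ratio of 1. CAAATG at shared regions, for instance, went from 0.804 to 1.008 within 50 bp of the summit. Within 50 bp of the summit, CACGTG (1.95) and CAGCTG (1.23) in the replicate 2 list no longer passed the threshold, and within 250 bp CACGTG did not in the lists of replicate 1 (1.16) and replicate 2 (1.48). Counted as the number of peaks, as planned, CACCTG in the replicate 1 list (1.70) and CACGTG at shared regions (3.17) passed. For these 6 changes the cause was not tested.

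With duplicates removed, 0 regions differed between replicates (chi-square test, 33 unadjusted) against 2; the cause was not tested. Input copy number at hlh-8 rose to 3.36 and 3.83 within 10 kb, where the narrower span leaves out bins near the median. In the limma bin fit, 0 bins were higher without a filter (3540 unadjusted); the cause was not tested. Leaving out 1 library gave 20 (without input replicate 1) to 261 (without ChIP replicate 2) higher bins, each lone library being assumed to vary like the other group; the low counts came with the loss of either input. With no replicate block there were 212 higher bins, so the paired block changed little. The other bin alternatives gave 180 to 255. The count of mesoderm domains with a region nearby was 3 within 5 kb (permutation p = 0.0025), and it no longer passed the threshold at 3 within 20 kb (p = 0.0539 by permutation), where random placement gives more, or at 2 without hlh-8 (p = 0.0615 by permutation), where fewer domains are tested.

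The settings drawn up for promoters, gene lists and peak position were not run, for want of gene positions on this build. CATATG and CACGTG at shared regions had no site in the flanks and so no value there. Depth limits single regions: the ratio of II:5877891-5878181 in replicate 1 had an interval of 4.78 to 50.7.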

Other observations

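Of the tests in this part, those of enrichment in the other replicate and of the earlier stage, the grouping of 3 E-boxes, the rate of any CANNTG in regions called in 1 replicate only, the hexamer and B-box tests and the comparison of GFP-coding reads were chosen after results were seen.

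Regions called in 1 replicate only made up most of the 259. Calls without binding at random places are argued against by their E-boxes: the smaller ratio of E-box rate to GC-matched windows in these sets was 3.45. The 3 E-boxes had been grouped from lists that include these regions, but they also ranked 1 to 3 of the 10 CANNTG hexamers at shared regions alone. Any CANNTG, a motif fixed beforehand, was 1.76 and 1.53 times as frequent in the sets as in matched windows. Its permutation p-values were 0.0001, the smallest the draws can give, and 0.003. The windows were not matched on input reads. GAGAGA, common at open promoters, was 2.44 and 3.23 times as frequent in the full lists of replicates 1 and 2. The rise of any CANNTG therefore cannot tell binding from open chromatin. Enrichment under the calling threshold in the other replicate may explain many of the regions called in 1 replicate only, since the smaller median ChIP over input there was 2.15. Sets of equally many regions outside peaks, matched on the calling replicate's input, had medians of at most 1.48 in replicate 1 and 1.43 in replicate 2, against 2.18 at the 40 and 2.24 at the 156 regions that could be matched (permutation p = 0.0001 for each, the smallest the draws can give). In the measured replicate the matched regions still held fewer depth-scaled input reads per kb, 16 against 22.4 in replicate 1 and 15.8 against 26 in replicate 2. The earlier stage of 1 replicate cannot be told apart from chance and preparation: 44 regions differed before adjustment, but every region was chosen on these libraries and the stage of each replicate is not stated.

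Input reads were also raised at the regions, at a median of 22 depth-scaled reads per kb at replicate 1 peaks in replicate 1 against 8.48 at random regions. Open chromatin that takes up reads in ChIP as in input could produce peaks, and it cannot be told apart from binding by this ratio: regions outside peaks matched on the other replicate's input had at most 0.436 of the median ChIP over input at peaks, but selection fixes that outcome, since they are the regions left uncalled. Windows outside peaks matched on input held the 3 E-boxes at 1.285 sites per 1000 positions, close to 1.315 in GC-matched windows. This was 0.222 times the 5.797 at the regions. It argues against E-boxes being common in open chromatin that was left uncalled, and covers no called region. The matched regions had somewhat lower input, 18.3 against 21.4 in replicate 1 and 16.6 against 25.4 in replicate 2. The design has no group that differs in chromatin, so no explanation beyond these was tested.

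In replicate 1, GFP-coding reads were 1.76 times (0.979 to 3.19) as frequent in ChIP as in input (exact binomial test, p = 0.0498), and in replicate 2 they were 0.948 times (0.420 to 2.10, p = 1 by the same exact test). These 2 p-values are unadjusted and the interval of the first includes 1, so no enrichment is taken from them. Of 2080 hexamers, 75 passed the threshold at the regions (232 unadjusted), with the highest z scores for CAGATG, CACATG and ACACAT. The B box of tRNA genes occurred within 250 bp of the summit at 0 of 216, 0 of 91 and 0 of 48 regions, against 0.861, 0.404 and 0.190 in matched windows. With so few expected, and only bases under unique reads searched, these counts cannot show whether B boxes are absent.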
